A study of Arabidopsis thaliana with 8 samples.

How the data were processed

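Total RNA from whole Arabidopsis thaliana seedlings, 6 days old, was measured on 8 arrays of the 1-colour Agilent kind, 4 for the tt8-3 line and 4 for its wild-type control. The labels place both lines in the Wassilewskija (Ws) background. The arrays lay on 2 slides, each with 2 arrays per line, and the design text of the series speaks of 2 biological replicates per line with technical replicates on each slide. The sample descriptions number the arrays of 1 slide together, so the 2 arrays of a line on a slide were taken as technical replicates and averaged, which leaves 2 against 2 biological replicates. The design text can also be read the other way, with the arrays at the same position on both slides as technical replicates, and that reading was run as an alternative chosen after seeing the data. Wild-type RNA lay in the first positions of each slide and tt8-3 RNA in the later ones, so position on the slide and genotype cannot be told apart.

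The scanner files hold spot intensities made with Agilent Feature Extraction 10.7.1.1, per the file headers: a processed signal (linear intensity, background-subtracted and detrended), the median intensity of each spot and of its local background, and 0 or 1 flags. Flags for spots well above background, saturated or uneven come from the same software, per the file headers. No spot was saturated. The deposited value table holds log2 values, and a check against the scanner files showed log2 of the processed signal scaled to the 75th percentile of each array and then centred per probe on the median of its slide (correlation at least 0.9999 over probes on every array). No steps beyond these are given in the sources used here.

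The main values were log2 of the processed signal minus the 75th percentile of the array, over 43603 probes without controls. Spots flagged as uneven or as outliers were left out (4 to 23 per array), and repeated spots of a probe were averaged. Probes were named by matching the transcript accession of each probe, without version, to the gene table given with the data (assembly TAIR10.1). This named 34358 probes by 1 gene and left 9245 probes unnamed. For a gene with several probes (6940 of 25433 genes), the brightest on average stood for the gene. A gene was tested when that probe was well above background on all 4 arrays of at least 1 genotype, which left 19227 genes.

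Signal over background limits the precision here, as does the number of arrays. The 75th percentile of the processed signal was 545 to 1108 per array. Between 69.0% and 71.7% of probes were well above background on wild-type arrays and between 70.9% and 77.3% on tt8-3 arrays. Where a gene was not well above background on any array of a genotype, its fold change is given as a lower bound, computed against the lowest signal called well above background on each array or the gene's own value if higher. Where the gene's own value was higher on each array, this bound equals the measured change. Such bounds hold for the main values only. TT8 had a smaller change with normexp. Every gene given such a bound below had a change under it in some fit with an array or biological replicate left out. The lowest log2 change in those fits was 2.70 for CRA1 (bound 3.28), 2.03 for FMO1 (bound 2.28) and 0.89 for MYB111 (bound 1.26). No pair of arrays held identical values beyond 2.29e-05 of probes.

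Genes were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The 2 biological replicates per line are few, and adjusted p-values measure the spread between these slide averages, part or all of which may be technical. With 8 arrays and the biological replicate as a random block, the consensus correlation within biological replicates was -0.207. This negative value means that, over both lines, arrays averaged as technical replicates were less alike than arrays of different slide averages. The lines differ in this, as given below. Gene lists (27, fixed before the data were examined, as were the fits, the rule for named genes and most other settings) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 25 lists that had at least 5 tested genes. The same test with an estimated correlation, and fry, were run beside it. Genes are named by a rule: TT8, the 10 largest rises and the 10 largest falls among genes past the threshold with the same direction on both slides, up to 4 members of each list with the smallest p, and every measured member of the anthocyanin, proanthocyanidin and MYB-bHLH-WD40 lists. One gene that the rule names is not reported here. The steps were tested on simulated data over 19227 genes. With 50 genes changed at each size, 0% were recovered at a log2 change of 0.5, 16% at 1, 82% at 2 and 98% at 3, and 9 of 107 calls were false. The list test recovered 20 of 20 lists of 20 genes shifted by 0.5, and called 1 of 380 unchanged lists. Simulated genes varied independently, without slide or position effects, so the list result does not test the preset inter-gene correlation. Few genes were changed, so the recovered shares do not carry over to data in which 5136 genes pass.

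The slide is a batch shared by both lines. The deviations of slide averages from their line's mean correlated at 0.78 over genes between the lines, so slide pairs the samples. The main fit does not use this pairing. The fit with slide as a block does, but has few residual degrees of freedom. It is given beside list calls that it ended and beside most list counts that it moved by over 1.5 times. The alternatives were quantile normalization, scaling to the median, normexp background correction with an offset of 50, the deposited value table, no filter on dim probes, detection on all 8 arrays, the block on slide, fits of the 8 arrays with and without the replicate structure, every probe tested with a majority call, eBayes with a trend and robust prior, other thresholds, and each array and each biological replicate left out. Normexp was planned on mean spot signals, which the files do not hold, and was run on median signals. Its fit failed on tt8-3 replicate 4, with a fitted background mean of -684 against 3.36 to 12.4 on the other arrays. That array held a patch of 14 spots with a local background up to 35326. All 14 spots carried the flag for uneven background. The planned fit was kept as run, and a second one without spots so flagged was added after seeing the data. Figures were drawn with matplotlib 3.10.9.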

Results

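Gene expression was measured in whole seedlings of tt8-3, a loss-of-function line of TT8, and of wild type, with 4 arrays per line on 2 slides. TT8 encodes a basic helix-loop-helix factor that activates flavonoid genes together with MYB and WD40 partners. The comparison asks which genes, among them those of metabolite glycosylation and stress hormone synthesis named in the title of the series, differ in level when TT8 is lost. Levels are log2 signal minus the 75th percentile of the array, and each of the 2 biological replicates per line is the mean of 2 arrays.

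TT8 (AT4G09820) was measured first as a check of the labels. Its level was 4.28 ± 0.065 in wild type and -6.41 ± 0.86 in tt8-3 (SD, n = 2), and its signal was not well above background on any of the 4 tt8-3 arrays. By the lower bound on the main values, the transcript was at least 1650-fold lower in tt8-3 (limma adjusted p = 0.0018). This bound equals the measured log2 change of -10.69. The change was smaller, at -7.73, with normexp background correction that leaves out spots of flagged background. A single probe reads TT8, and its place relative to the insertion is not known here.

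By slide averages, most jasmonate genes tested rose in tt8-3. Of 23 jasmonate response genes 16 rose and 1 fell, with a median log2 change of 1.37, and of 17 jasmonate biosynthesis genes 11 rose and 1 fell, with a median of 1.12. Of 54 WRKY genes 21 rose and 2 fell, and of 12 phenylpropanoid and monolignol genes none rose and 5 fell. None of these 4 lists passes with an estimated correlation (adjusted p = 0.36 for each). When arrays were averaged by position, as described below, 7 jasmonate response, 6 jasmonate biosynthesis and 1 WRKY genes rose and 0 phenylpropanoid genes fell. Across the 19227 genes tested, 5136 passed the threshold, 3024 higher and 2112 lower in tt8-3.

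**Figure D1:**
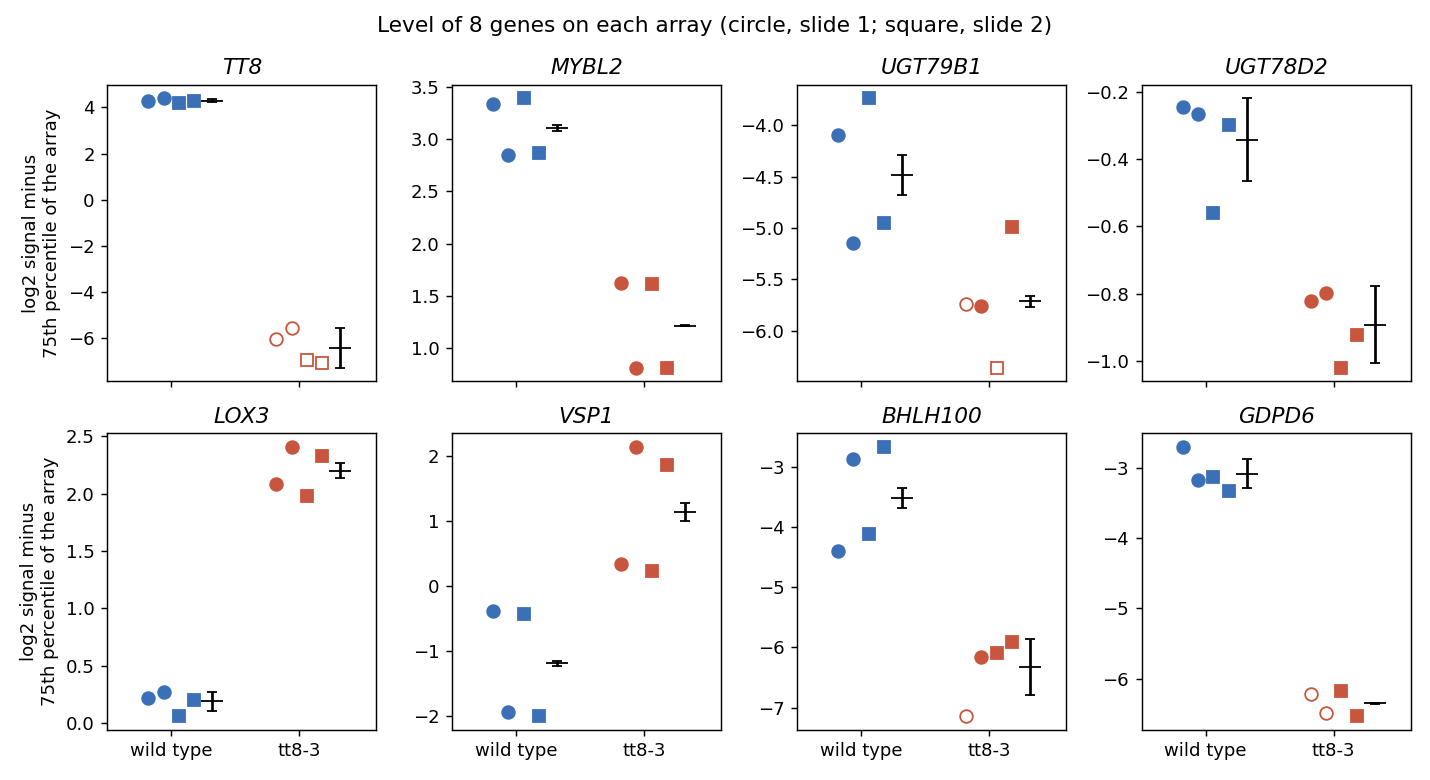
Level of 8 genes on each array, as log2 signal minus the 75th percentile of the array. Circles are slide 1 and squares slide 2, open symbols are not well above background, and the bar with whiskers is the mean and SD of the 2 biological replicates. TT8 sits near 4.28 in wild type and is not well above background in tt8-3, and for MYBL2 and VSP1 replicates 1 and 3 lie together, apart from replicates 2 and 4, in both lines.

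The number of changed genes depends on which arrays count as technical replicates. When the arrays at the same position on both slides were averaged, 597 genes passed, 524 higher and 73 lower. Of these, 573 were among the 5136. Both averagings use the same arrays of each line and give nearly the same log2 changes. They differ in the spread, so a shared direction is no further evidence. With slide as a block on averaged values, the block fit meant throughout, 12413 genes passed, 6494 higher and 5919 lower, which include all 5136. With the same block on the 8 single arrays, which counts technical replicates as separate, 6593 passed, 3894 higher and 2699 lower. In wild type the difference between the 2 arrays of slide 1 correlated with that of slide 2 at 0.88 over genes, and in tt8-3 at 0.67. Arrays of 1 position were closer than arrays of 1 slide in wild type (median absolute deviation 0.22 against 0.47), and the order was the other way round in tt8-3 (0.26 against 0.20). Of the 128 genes named by rule besides TT8, 103 passed in the main fit, and 74 of these 103 lost their call under the averaging by position. Of the 25 that did not pass in the main fit, 20 passed with slide as a block. With normexp background correction that leaves out spots of flagged background, 20 of the 103 lost their call. In at least 1 of the 12 fits that leave out 1 array or biological replicate, 44 of the 103 lost it. Of those 12 fits, the call below was kept in 1 for PAL1, 2 for UXS5, 3 for UGT78D2, 4 for CYP79B2, 5 for CYP90D1, 6 for LBD39, BAS1 and UGT73C5, 7 for PYK10 and 8 for BCAT4, MYB34, TOC1 and PRR7. With the median in place of the 75th percentile, 2153 genes were higher and 2597 lower, so the balance of directions rests on the scaling. Leaving out 1 wild-type array gave 2282 to 2963 genes.

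In the jasmonate pathway, LOX3 (AT1G17420), a lipoxygenase of jasmonate synthesis, rose by 2.01 on the log2 scale (SE 0.096, adjusted p = 0.0026), and AOC1 (AT3G25760), an allene oxide cyclase, rose by 2.44 (SE 0.10, adjusted p = 0.0019). OPCL1 (AT1G20510), which activates a jasmonate precursor, rose by 1.299, and JMT (AT1G19640), which methylates jasmonate, was at least 9-fold higher, since no wild-type array detected it. Among response genes, MYC2 (AT1G32640), the central transcription factor of the pathway, rose by 1.37, CYP94C1 (AT2G27690), which oxidises the active hormone, by 1.92, JAZ1 (AT1G19180), a repressor of the response, by 1.62 and VSP1 (AT5G24780), a vegetative storage protein, by 2.34. JAZ1 (adjusted p = 0.054) and VSP1 (adjusted p = 0.17) did not pass under the averaging by position, where 7 response and 6 biosynthesis genes rose. Camera gave an adjusted p = 4.8e-05 for response and 0.0033 for biosynthesis, and each had an adjusted p = 0.36 with an estimated correlation.

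Of 13 salicylic acid defence genes 7 rose and 1 fell (median 0.84, camera adjusted p = 0.033, adjusted p = 0.36 with an estimated correlation). SARD1 (AT1G73805), a regulator of salicylic acid synthesis, rose by 1.104, PR5 (AT1G75040), a pathogenesis-related protein, by 1.06, EDS5 (AT4G39030), a transporter of that pathway, rose from a level of -2.75 to -1.55, and FMO1 (AT1G19250) was at least 4.87-fold higher. Under the averaging by position 1 gene of the list rose and 1 fell, and SARD1 (adjusted p = 0.18), PR5 (0.185) and EDS5 (0.054) did not pass. The list lost its call with slide as a block (adjusted p = 0.0501), under the averaging by position (adjusted p = 0.058) and with quantile normalization (adjusted p = 0.062), and kept it in 11 of the 12 fits that leave out an array or replicate. WRKY40 (AT1G80840) rose by 1.26, WRKY18 (AT4G31800) by 1.25, WRKY33 (AT2G38470) by 1.40 and WRKY53 (AT4G23810) by 1.64, all factors of defence responses, and none of these 4 passed under the averaging by position (adjusted p 0.071 to 0.18). With slide as a block 31 WRKY genes rose and 5 fell. The WRKY list had a camera adjusted p = 0.0033, and adjusted p = 0.36 with an estimated correlation, and kept its call in 11 of the 12 fits that leave out an array or replicate.

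**Figure D2:**
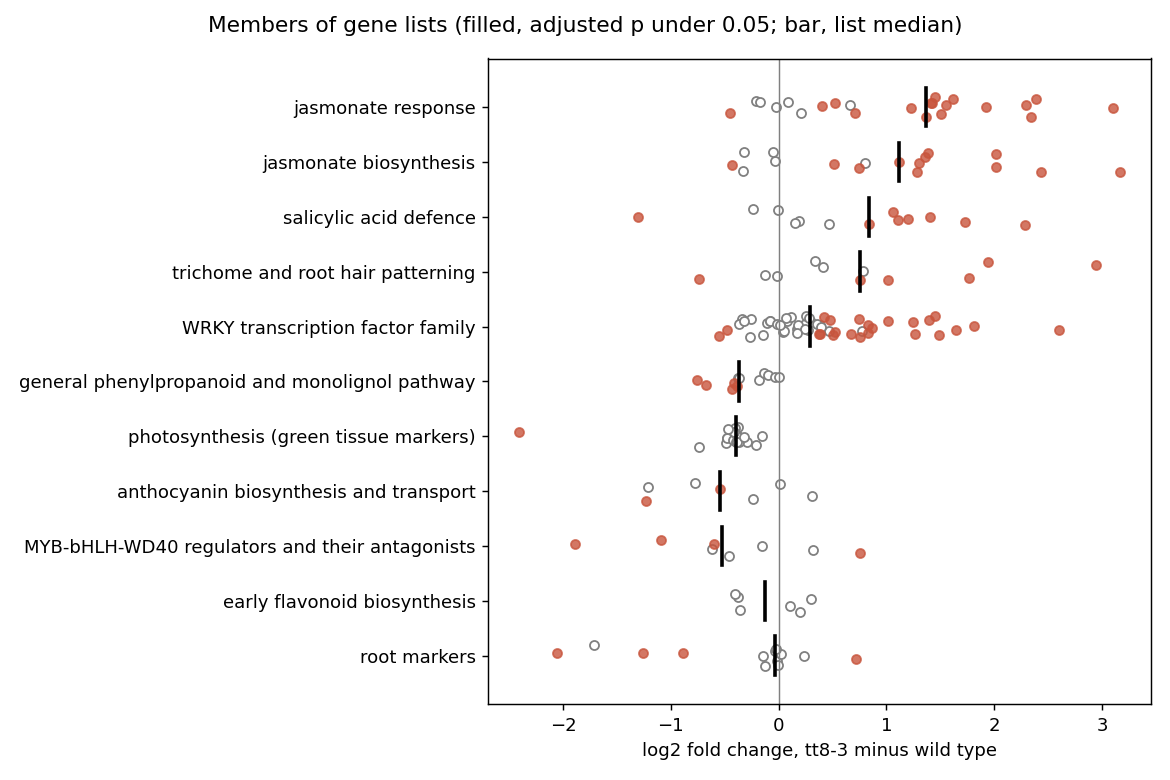
Log2 change between tt8-3 and wild type (horizontal axis) of each tested member of 11 gene lists. Filled points passed the threshold and bars are list medians. TT8 itself is not drawn. Jasmonate response has its median at 1.37, photosynthesis at -0.40.

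Of 16 listed regulators that act with or against TT8, 8 were tested, of which 1 rose and 3 fell (median -0.53, camera adjusted p = 0.080). The list had an adjusted p = 0.014 with fry and 0.36 with an estimated correlation. MYBL2 (AT1G71030), a repressor of anthocyanin synthesis, fell by 1.89 (SE 0.083, adjusted p = 0.0022), LBD37 (AT5G67420) by 1.09 and LBD39 (AT4G37540) by 0.60, both repressors of the same pathway, while CPC (AT2G46410), a small MYB factor of epidermal patterning, rose by 0.76. None of these 4 passed under the averaging by position, where MYBL2 had an adjusted p = 0.070. MYB75 (log2 change -0.46), LBD38 (-0.62), EGL3 (0.32) and TTG1 (-0.16) did not pass the test, though the first 3 of these passed with slide as a block (adjusted p = 0.0065, 0.0054 and 0.012), where 2 regulators rose and 5 fell. With 1 array or replicate left out, the change of MYB75 was -0.67 to -0.25, of LBD38 -0.91 to -0.33, of EGL3 0.11 to 0.53 and of TTG1 -0.26 to -0.050.

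Of 10 listed anthocyanin synthesis and transport genes 7 were tested. None of these rose and 2 fell (camera adjusted p = 0.099). The list had an adjusted p = 0.025 with fry and 0.36 with an estimated correlation. Its median was -0.55, or -0.61 to -0.21 with 1 array or replicate left out. UGT79B1 (AT5G54060), an anthocyanin xylosyltransferase, fell by 1.23, with a signal well above background on 2 of 4 tt8-3 arrays, and UGT78D2 (AT5G17050), a flavonoid glucosyltransferase, fell by 0.55. Neither passed under the averaging by position (adjusted p = 0.20 and 0.13). DFR (0.31), TT19 (0.02), UGT75C1 (-0.24), 3AT1 (-0.78) and SCPL10 (-1.22) did not pass. With slide as a block 4 genes fell, 3AT1 (adjusted p = 0.031) and SCPL10 (0.0022) among them, and SCPL10 also passed under the averaging by position (adjusted p = 0.038). Leaving out 1 array or replicate moved 3AT1 over -1.46 to -0.097, SCPL10 over -1.67 to -0.76 and UGT75C1 over -0.48 to -0.0062. Of 6 listed genes of the proanthocyanidin branch 2 were tested. TT15 (AT1G43620) fell by 0.77 and TTG2 (AT2G37260) rose by 1.01, and neither passed under the averaging by position (adjusted p = 0.16 and 0.11). None of 6 early flavonoid genes passed (camera adjusted p = 0.55), among them F3H (-0.35), FLS1 (-0.40), CHIL (-0.38) and the flavonoid 3'-hydroxylase TT7 (0.30). With slide as a block 2 of the 6 rose and 3 fell, and these 4 named genes passed (adjusted p 0.0062 to 0.011). Their changes moved when an array or replicate was left out, F3H from -0.54 to -0.16, FLS1 from -0.63 to -0.18, CHIL from -0.54 to -0.22. Of 6 flavonol genes 2 rose and 1 fell (camera adjusted p = 0.49, fry adjusted p = 0.015, adjusted p = 0.60 with an estimated correlation). With slide as a block 2 rose and 4 fell, and under the averaging by position 1 rose and 0 fell. The median was -0.37 (-0.49 to -0.21 with 1 array or replicate left out) while the mean was 0.37. UGT78D1 (AT1G30530), a flavonol rhamnosyltransferase, rose by 2.71, and MYB111 (AT5G49330), an activator of flavonol synthesis, was at least 2.39-fold higher, a call that was lost under the averaging by position (adjusted p = 0.14) and kept in 5 of 12 fits with an array or replicate left out. The phenylpropanoid list (median -0.37, or -0.44 to -0.21 with 1 array or replicate left out, camera adjusted p = 0.0089, adjusted p = 0.36 with an estimated correlation) includes CCR1 (AT1G15950), which fell by 0.67, F5H (AT4G36220), by 0.76, and PAL1 (AT2G37040), by 0.43, and none of these passed under the averaging by position, with the call of PAL1 kept in 1 of 12 fits with an array or replicate left out.

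Glycosyltransferases of the UGT family went both ways, with 10 higher and 17 lower of 53 (camera adjusted p = 0.11). Under the averaging by position 1 was higher and 0 lower, and with slide as a block 15 were higher and 25 lower. UGT85A2 (AT1G22360) rose by 1.00, UGT72B3 (AT1G01420) by 0.95 and UGT71C3 (AT1G07260) by 0.83, and these did not pass under the averaging by position (adjusted p = 0.069, 0.20 and 0.11). Of 27 nucleotide sugar genes 1 rose, UXS5 (AT3G46440), by 0.43, and 1 fell, UGP1 (AT3G03250), by 0.68, and the median of 0.03 (-0.14 to 0.058 with 1 array or replicate left out) and mean of -0.09 differed in sign (adjusted p = 0.29). UER1 (-0.51) and USP (-0.47) did not pass. In the fit with slide as a block 3 genes rose and 10 fell, UER1 (adjusted p = 0.0091) and USP (0.027) among them, and under the averaging by position 0 passed.

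Other hormone and defence lists did not pass as lists with camera. Of these, only the aliphatic glucosinolate list passed with fry (adjusted p = 0.022). In the abscisic acid and cold list (1 rose, 1 fell of 14, adjusted p = 0.38), RD29A (AT5G52310), a stress-induced gene, rose by 1.69, and ABA1 (AT5G67030), an enzyme of abscisic acid synthesis, fell by 1.09. RAB18 (0.32) and KIN2 (0.54) did not pass, but did with slide as a block (adjusted p = 0.0093 and 0.0053), where 7 genes rose and 2 fell. Leaving out 1 array or replicate gave 0.018 to 0.61 for RAB18 and 0.35 to 0.73 for KIN2. ABA1 did not pass under the averaging by position (adjusted p = 0.053). Of 16 brassinosteroid genes 2 rose and 2 fell (adjusted p = 0.18), with BR6OX1 (AT5G38970) falling by 1.31, while CYP90D1 (AT3G13730) rose by 0.58 (0.38 to 0.78 with 1 array or replicate left out) and BAS1 (AT2G26710) by 0.77. The other fall, of UGT73C5 (AT2G36800), was 0.78 in the mean, but replicates 1 and 3 were higher in tt8-3 (1.46 and 1.37) than in wild type (0.87 and 0.72), and its log2 change was -1.31 to -0.26 when 1 replicate was left out. None of the 16 passed under the averaging by position, and with slide as a block 2 rose and 6 fell. Aliphatic glucosinolate genes had 3 rises and no falls of 13 (adjusted p = 0.058), among them MAM1 (AT5G23010) by 2.01 and BCAT4 (AT3G19710) by 1.21, both of side chain elongation. Neither passed under the averaging by position (adjusted p = 0.13 and 0.36), where 0 genes of the list rose, and the change of BCAT4 was 0.64 to 1.79 when 1 replicate was left out. The block on slide gave 9 rises and 1 fall. The indolic list had 1 rise, MYB34 (AT5G60890) by 0.78, and 1 fall, CYP79B2 (AT4G39950) by 0.58, of 10 (adjusted p = 0.45), against 3 and 6 with slide as a block and 0 under the averaging by position.

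Enzyme families split. Of 42 glutathione S-transferases 2 rose and 9 fell (adjusted p = 0.057), with GSTU8 (AT3G09270) rising by 2.63 and GSTL1 (AT5G02780) falling by 1.53. The block on slide gave 9 rises and 20 falls, and under the averaging by position 1 rose and 0 fell. Of 155 cytochrome P450 genes 21 rose and 35 fell (adjusted p = 0.27), and CYP705A27 (AT1G50520) was at least 30.1-fold higher. The block on slide gave 47 rises and 58 falls, and under the averaging by position 5 rose and 5 fell. Of 26 xyloglucan endotransglucosylases 5 rose and 6 fell (adjusted p = 0.32), or 8 and 12 with slide as a block. Of 25 heat shock genes 8 rose and 5 fell (median -0.14, mean 0.22, adjusted p = 0.92), and of 11 class III peroxidases 3 rose and 1 fell (median -0.05, mean 0.06, adjusted p = 0.90). In the fit with slide as a block 10 heat shock genes rose and 10 fell, and 4 peroxidases rose and 3 fell. Under the averaging by position 1 gene of these 3 families, a peroxidase, rose and 0 fell.

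Markers of organs and of harvest time were compared as well. At the probe used for each, all 20 photosynthesis genes were lower on both slides, and 19 of them fell in the fit with slide as a block (camera adjusted p = 0.00013). In the main fit 1 passed, LHCB2.1 (AT2G05100). It fell by 2.41 at the probe used but rose by 1.01 in the median over its 2 probes, so its direction differs between probes. The list median was -0.40 (camera adjusted p = 0.0081, adjusted p = 0.60 with an estimated correlation and 0.24 with fry). LHCB2.1 did not pass under the averaging by position (adjusted p = 0.072). Under quantile normalization the list median was -0.04 (adjusted p = 0.27), and with 1 array or biological replicate left out it was -0.76 to -0.073, with the call kept in 9 of 12 fits. Of 13 root markers 1 rose and 3 fell (median -0.03, or -0.34 to 0.066 over arrays and replicates left out, adjusted p = 0.28), and NRT2.1 (AT1G08090), a nitrate transporter, fell by 2.05, while PYK10 (AT3G09260) rose by 0.71. PYK10 did not pass under the averaging by position (adjusted p = 0.30), where 0 root markers rose and 2 fell, and its change was 0.46 to 0.96 over arrays and replicates left out. Of 11 trichome and root hair genes 5 rose and 1 fell (camera adjusted p = 0.043, adjusted p = 0.36 with an estimated correlation), among them GL1 (AT3G27920), GL2 (AT1G79840) by 1.77 and MYB23 (AT5G40330) by 1.94. GL1 was well above background on 1 of 4 wild-type arrays, so its change of 2.94 rests mostly on signals not well above background there. Under the averaging by position 1 gene of the list rose, GL1, and with slide as a block 8 rose and 1 fell. That list lost its call with slide as a block (adjusted p = 0.068), under the averaging by position (adjusted p = 0.065) and in 3 of the 12 fits that leave out an array or replicate, where its median was 0.35 to 0.89. Of 11 clock genes 1 rose, TOC1 (AT5G61380) by 0.66, and 3 fell (adjusted p = 0.099), RVE8 (AT3G09600), GI (AT1G22770) by 0.73 and PRR7 (AT5G02810) by 0.60. RVE8 was well above background on 1 of 4 tt8-3 arrays, so its change of -1.098 rests mostly on signals not well above background there. In the fit with slide as a block 6 clock genes fell, and under the averaging by position 1 did, RVE8, while TOC1 did not pass (adjusted p = 0.12). Of 12 listed seed storage genes 4 were tested. Of these 3 rose, among them CRA1 (AT5G44120), a storage globulin that was at least 9.71-fold higher, and 0 passed under the averaging by position. Of 9 sugar response genes 1 rose, SEN1 (AT4G35770) by 1.37, and 4 fell (adjusted p = 0.13), with SWEET15 (AT5G13170), a sugar exporter, falling by 2.64 and GPT2 (AT1G61800) by 1.39, and 0 of the 9 passed under the averaging by position.

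The largest differences were mostly rises. Of the genes past the threshold, 157 were higher and 2 lower by at least 3 on the log2 scale. AT4G34881 was at least 1750-fold higher in tt8-3, ECS1 (AT1G31580) at least 987-fold, AT5G05060 at least 934-fold, AT1G66090 at least 717-fold and ZW9 (AT1G58270) at least 563-fold. HR4 (AT3G50480), a relative of a mildew resistance gene, was at least 378-fold higher, AT1G66100 at least 363-fold, AT2G04378 at least 287-fold and AT3G47250 at least 276-fold. AT1G25141 rose by 8.94 on the log2 scale, but was well above background on 1 of 4 wild-type arrays, so that size is not ranked. In all, 239 genes were well above background on all tt8-3 arrays and on no wild-type array, against 2 the other way round, TT8 and AT4G29103. Among genes with several probes, 50 had 1 probe that differed by at least 2 on the log2 scale between lines while another differed by under 0.5, and in 49 of them the differing probe was the lower in wild type.

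**Figure D3:**
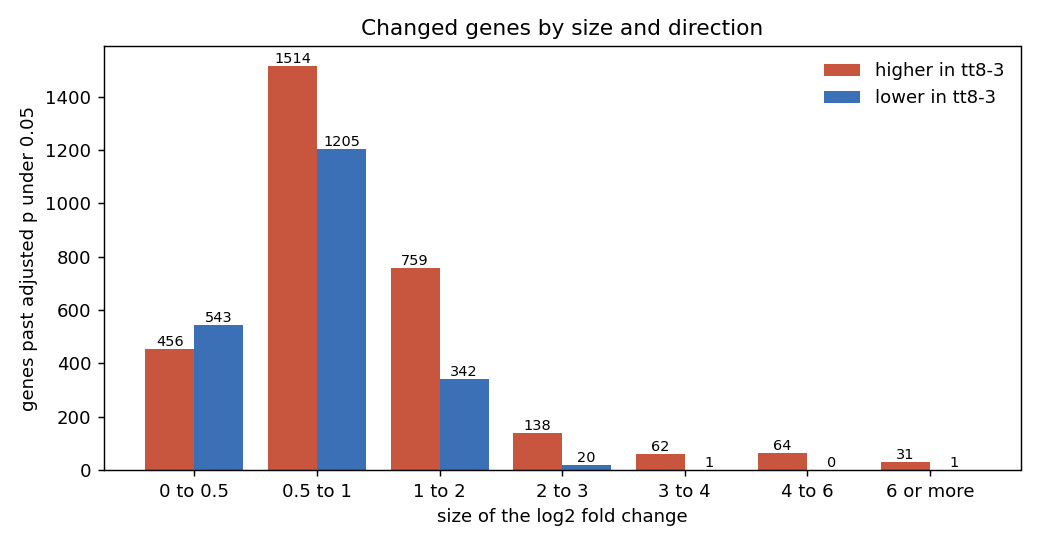
Number of genes past the threshold (vertical axis) by size of the log2 change (horizontal axis), higher and lower in tt8-3. In the bin from 2 to 3 there are 138 higher and 20 lower genes.

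Among the large falls after that of TT8, those with a signal well above background on all 8 arrays include BHLH101 (AT5G04150), a factor of the iron deficiency response, by 2.74, SUC7 (AT1G66570), of a sucrose carrier family, by 2.64, AT5G20670 by 2.45 and OFP16 (AT2G32100) by 2.42. BHLH100 (AT2G41240), a relative of BHLH101, fell by 2.81 and was well above background on 3 of 4 tt8-3 arrays. GDPD6 (AT5G08030), a glycerophosphodiester phosphodiesterase, AT1G29090 and AT2G27535 also fell, but were well above background on 2, 2 and 1 of 4 tt8-3 arrays, so their changes of -3.27, -2.68 and -2.71 are not ranked. Under the averaging by position BHLH100 (adjusted p = 0.077), AT2G27535 (0.071), SUC7 (0.11), SWEET15 (0.12) and OFP16 (0.065) did not pass.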

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

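The tests of green tissue and of the splits of the samples were chosen only after the result was seen. In 284 groups of 4 arrays, 4 values lay far from the other 3. The cut-off used gives 1 in 20 for independent values. Arrays of a group are related, as are genes and lists, so the count cannot be compared with that rate. The median level of the salicylic acid list was -2.55 on wild-type replicate 1 against -2.82 to -2.78 on the others. The median of the cytochrome P450 family was -1.63 on tt8-3 replicate 3 against -1.79 to -1.78. BAS1 had a level of -1.66 on tt8-3 replicate 4 against -1.07 to -0.98, and KIN2 one of 6.94 on tt8-3 replicate 2 against 6.26 to 6.37. Among the 9245 probes that no gene names, which no comparison uses, 145 were well above background on all tt8-3 arrays and on no wild-type array, against 1 the other way round.

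The first pattern is that 239 genes were detected in tt8-3 only and 2 in wild type only. A region linked to TT8 is argued against as the whole source, since 4.18% of the 239 genes lie within 500 annotated genes of TT8 (against 1.86% of tested genes, so it may be the source of a part). So is a higher sensitivity of the tt8-3 arrays, since the median lower bound of the difference is 2.99 on the log2 scale. Sensitivity may be the source of a part, since the lower quartile of that bound is 1.71 and 164 of the 239 genes reach 4-fold. A sequence difference between the wild-type material and the probes stays open: the differing probe was the lower in wild type in 98% of the 50 genes with disagreeing probes (95% exact interval 89.35% to 99.95%). A candidate explanation is therefore that the lines do not share 1 background. Part of the 3024 higher and of the 2112 lower genes may then reflect background and not TT8. Without the one-genotype genes and genes with disagreeing probes, 4865 genes passed, 2781 higher and 2084 lower. Leaving those genes out does not remove other differences of background, so the remaining genes of either direction are not free of them.

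The second pattern is that wild-type arrays at the same position on the 2 slides resemble each other more than arrays of 1 slide do, while tt8-3 arrays do not: their median absolute deviation was 0.26 by position and 0.20 by slide, and their between-slide differences correlated at 0.79. The same RNA at the same position may still be the source, since the smaller of the 2 correlations of within-slide differences was 0.67, but the tt8-3 values do not single it out. A brightness-dependent trend of single arrays is argued against, since that correlation was 0.67 after loess on signal level as well (0.6652). An effect of the position itself was not tested and stays open. If the same-position arrays are the technical replicates, 597 genes pass and not 5136. The adjusted p-values of the main fit would then rest on differences between slides and not between biological replicates.

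The third pattern is the rise of jasmonate genes. A sequence difference under single probes is argued against for 10 of the 27 genes called higher. Of their 16 other detected probes, 100% changed the same way by at least 0.5 of the size. The rest of the 27 had no other detected probe, so this was not tested for them. A lower share of green tissue cannot be told apart, since root markers had a median of -0.0321 with 3 falls and 1 rise, of PYK10, that was lost under the averaging by position (adjusted p = 0.30). All 20 photosynthesis genes were lower on both slides at the probes used, though LHCB2.1 rose in the median over its 2 probes. A different harvest time cannot be told apart either: morning minus evening clock genes gave -0.26, and evening genes went both ways. A background difference that changes jasmonate levels was not tested, so an effect of TT8 stays a hypothesis.

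The real split of the 4 biological replicates gave 5136 genes with limma and the highest of the others 0, so 1 of 3 splits, the real one, reached that count, and 3 splits are too few for a share under 0.05.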

How the results depend on the processing

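The normexp fit without flagged spots, the averaging of arrays by position and the leaving out of one-genotype genes were chosen after seeing the data. TT8 kept its direction and passed under every alternative in which it was tested, with log2 changes of -11.3 to -6.94. It was not tested where detection on all 8 arrays was asked for or where one-genotype genes were left out. Signal over background limits the size of changes measured at dim probes, and the causes of the shifts below were not tested except where stated.

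The 5136 changed genes (3024 higher, 2112 lower) became 597 (524 higher, 73 lower) when arrays at the same position were averaged. With slide as a block on averaged values the count was 12413 (6494 higher, 5919 lower), and in the list tests this block ended 2 calls, salicylic acid defence and trichome and root hair patterning, and no other. It brought 20 of 25 named genes that had not passed past the threshold. The deposited value table, which centres each probe within its slide, gave 13890 (7186 higher, 6704 lower). Without a filter on dim probes there were 2398 (1573 higher, 825 lower) among 25433 genes tested. A change of at least 2-fold left 1418 (1054 higher, 364 lower), and an adjusted p under 0.1 gave 3287 lower genes. Leaving out 1 array or 1 biological replicate gave 2096 to 5033 genes, 1487 to 2967 higher and 603 to 2066 lower, where a line left with 1 biological replicate is assumed to vary like the other. Without wild-type replicate 1, 2, 3 or 4 the count was 2508, 2799, 2282 or 2963, and without wild-type biological replicate 1 or 2 it was 2118 or 2096. Without tt8-3 replicate 1 the lower genes were 1330, and without tt8-3 biological replicate 1 or 2 they were 1342 or 1396.

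Normexp as planned gave 105 genes (91 higher, 14 lower), with a shift of the median of all genes to 0.12, and 11 lists. This is a failed fit on tt8-3 replicate 4, where the fitted background mean was -684, and not a property of the other arrays. Without spots of flagged background that mean was 4.51 and the count 3613 (1944 higher, 1669 lower), with 5 lists. On that array 82 spots were so flagged, among them the 14 with a high local background, which were not left out alone. The planned normexp fit also turned the direction of CHIL (0.22), FLS1 (0.051), UGT79B1 (0.21), UGT75C1 (0.42), 3AT1 (0.31), MYB75 (0.34), XTH14 (0.15), PRP3 (0.20), RVE8 (0.38) and GSTL1 (0.070), none of which turned in the fit without flagged spots, and the early flavonoid list (median 0.25).

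The 7 called lists became 4 with quantile normalization, 2 with 8 arrays and the biological replicate as a random block, 0 with an estimated correlation (lowest adjusted p 0.36) and 12 with fry. Fry gained 6 lists and lost 1, photosynthesis (adjusted p = 0.24). Those gained were anthocyanin (adjusted p = 0.025), MYB-bHLH-WD40 regulators (0.014), flavonol (0.015), aliphatic glucosinolate (0.022), sugar response (0.022) and clock (0.047). Leaving out 1 array or biological replicate gave 6 to 11. Of the lists not called, the heat shock test changed direction with quantile normalization (median -0.056), the median scaling (-0.24), no dim filter (-0.15) and, at a median of -0.14, in the fits of 8 arrays, with averaging by position and with fry, and its median ranged from -0.17 to 0.092 over replicates left out. The class III peroxidase test changed direction at a median of -0.049 in the fits of 8 arrays, with averaging by position and with fry, with a range of -0.14 to 0.088 over replicates left out. The aliphatic glucosinolate median ranged from -0.073 to 0.62 over those.

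Among named genes, TT19 was -0.12 with quantile normalization, -0.083 with median scaling, -0.13 in normexp without flagged spots and -0.38 over all its probes, and -0.34 to 0.38 over replicates left out. DFR was -0.0050 in normexp without flagged spots and -0.088 to 0.70 over replicates left out, EM6 was -0.44 to 0.73 over those, LHCB3 was 0.030 with quantile normalization and LHCB2.1 was 1.01 over all its probes. Under the averaging by position 74 of the 103 named genes that had passed, TT8 left aside, no longer did. With TT8, 30 of 104 passed in both averagings. The 53 of 128 named genes that kept their side of the threshold include genes that passed in neither.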

Other observations

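The iron deficiency genes below were looked at after BHLH100 and BHLH101 stood among the largest falls. All 4 factors of subgroup Ib fell in tt8-3: BHLH38 (AT3G56970) by 1.91, BHLH39 (AT3G56980) by 2.25, BHLH100 by 2.81 and BHLH101 by 2.74 on the log2 scale. Of 10 other iron deficiency genes 4 fell and 2 rose. FRO2 (AT1G01580), the root ferric reductase, fell by 1.76, OPT3 (AT4G16370), a transporter, by 0.87, and the peptide genes IMA1 (AT1G47400) and IMA2 (AT1G47395) by 0.67 and 0.74. PYE (AT3G47640), a regulator of the response, rose by 0.80, and NAS4 (AT1G56430), a nicotianamine synthase, by 0.79. IRT1 (AT4G19690), the iron transporter, had a log2 change of -1.71 (SE 0.96) that did not pass.

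A hypothesis is a lower iron deficiency response in tt8-3. The median of the 10 other genes was -0.52, under the bound of -0.3 set before it was computed, which is consistent with that hypothesis, though PYE and NAS4 rose and the fall of BHLH100 did not pass under the averaging by position (adjusted p = 0.077).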
